A study of Homo sapiens with 3 samples.

How the data were processed

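RNA was measured in AGS cells, a human gastric adenocarcinoma line, cultured for 48 h with DMSO as the vehicle control, with 12 µM of a compound named SFA or with 18 µM of a compound named SFE. The labels give 1 library per group, so the 3 libraries have no replicates and no paired design. Per the labels' protocols, total RNA was extracted with TRIzol and depleted of ribosomal RNA before Illumina libraries were made. What the code names SFA and SFE stand for was not given in the sources used here.

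Per the submitters' processing notes, HISAT2 2.0.4, StringTie 1.2.3 and the hg38 genome build were used, and the notes as available here give neither their roles nor their order. The counting tool, its strand setting, the annotation release and any read filter were not given in the sources used here. The authors deposited 1 table of 50868 genes with raw counts and FPKM (fragments per kilobase of gene length, scaled to the library's total) for each library. The deposited counts were whole numbers. The deposited FPKM was the count divided by 1 length per gene and by the library's total count: among 22070 genes with counts in all 3 libraries, the lengths implied by different libraries differed by at most 0.0831%. FPKM therefore carries the counting error of the counts and is not corrected for composition or length bias.

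Gene names were taken from the table by Ensembl identifier. A current symbol was found for 97.6% of the identifiers and a GENCODE 29 biotype for 98.5%. Of the identifiers matched to GENCODE 29, 100% lay on the same chromosome and 94.9% had the same start and end, so coordinates are given on hg38. Of all listed genes, 56.1% overlapped another listed gene. Because the use of strand in counting was not given, reads from overlapping or antisense genes, and from near-identical copies, cannot be told apart with certainty, and values of such genes are uncertain.

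FPKM was used as deposited. Where several identifiers shared a gene name (470 of them), the one with the highest mean FPKM was kept. Genes at 1 FPKM or more in at least 1 library entered, which left 11680 genes, of which 9444 were protein-coding. Differences are log2(FPKM + 1) in one library minus the same in the other, which understates the change of genes with low values, and a gene was counted as higher or lower at a difference of at least 2-fold on that scale. Folds quoted for single genes are ratios of deposited counts, each divided by its library's total count, with 95% intervals from the exact conditional (Clopper-Pearson) binomial method. Reads were not counted by molecular identifier, so these intervals cover counting error only and say nothing about the spread between cultures. A gene at 0 counts was given a lower bound of the fold from a floor of 3 counts in that library, which is 0.160 CPM with DMSO and 0.220 with SFA and with SFE. With 1 library per group no test between conditions was possible and no p-value was computed.

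A total of 38 gene lists was fixed before the data were examined, together with the comparisons, the 2-fold limit and the rule for naming genes. They covered DNA replication, mitosis, replication-dependent histones, DNA damage repair, p53 targets, the integrated stress response, endoplasmic reticulum chaperones, the heat shock response, NRF2 targets, AhR targets, metallothioneins, cholesterol synthesis, fatty acid synthesis, the interferon response, NF-kB targets, hypoxia and glycolysis, apoptosis promoters and inhibitors, autophagy and lysosome, proteasome subunits, tubulins, epithelial and mesenchymal markers, Wnt targets, YAP targets, MAPK feedback targets, immediate early genes, ribosome biogenesis and MYC targets, ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, gastric and intestinal differentiation, small nuclear and nucleolar RNA, and markers of fibroblasts, leukocytes, erythroid cells, endothelial cells and hepatocytes. For each list with at least 5 measured members the median log2 difference was placed as a percentile among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart below percentile 0.5 or above percentile 99.5. The percentile describes these libraries and is not a test of the treatment.

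Genes were named by a rule: for each compound against DMSO, the 10 protein-coding genes with the largest positive and the 10 with the largest negative difference among those at 5 FPKM or more in the higher library; for SFE against SFA, the 5 largest each way; up to 4 members of each list with the largest difference; and 15 genes whatever their values. This named 165 genes, of which the most informative are described, and some are not reported here. The overlap and the covariance of both differences from DMSO were set beside 100 simulations, since both differences share the same DMSO library. In these, the 3 libraries differed by independent noise only, as large in each library as the SFE minus SFA differences imply.

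On simulated counts for 11255 genes with 200 changed by known folds, the 2-fold limit called 26% of genes changed 2-fold and 98% of genes changed 4-fold in the SFA comparison, 26% and 100% in the SFE comparison, and 0.299%, 0.271% and 0.364% of unchanged genes in SFA against DMSO, SFE against DMSO and SFE against SFA. Of 200 simulated lists of unchanged genes, 1%, 0.5% and 0.5% stood apart in these 3 comparisons, and 100% of lists shifted by 0.3 on the log2 scale did so. The simulation set a coefficient of variation of 0.1 between libraries and drew genes independently, and no replicate was there to check either setting. These rates are therefore not error rates of the present libraries or of lists of co-regulated genes.

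Alternatives covered other pseudocounts, low-value filters and fold limits, 3 scalings of the libraries, protein-coding genes alone, deposited counts in place of FPKM, summing identifiers that share a name, random lists drawn without matching, and a protein-coding background. Leaving out genes that overlap another gene, leaving out genes at 0 counts in 1 library and at 50 or more in another, asking that the whole counting interval exceed 2-fold, and matching random lists on gene length as well as expression (8 bins each) were added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.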

Results

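Gene expression was measured by RNA sequencing in AGS gastric adenocarcinoma cells after 48 h with DMSO, 12 µM SFA or 18 µM SFE, with 1 library each. Total counts were 18767232 with DMSO, 13639844 with SFA and 13644676 with SFE. Protein-coding genes took 94.5%, 94.7% and 94.4% of the counts, and 10641, 10708 and 10916 genes reached 1 FPKM. No library has a replicate, so every difference compares single libraries and cannot be set against the spread between cultures, and intervals show counting error only.

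The comparison of SFA with DMSO asked how the transcriptome of AGS cells differed after exposure to SFA. Targets of NRF2, the transcription factor that answers oxidants and electrophiles, were higher in the SFA library. AKR1C1, an aldo-keto reductase on chromosome 10 (4963253 to 5107522), stood at 8.63 FPKM with DMSO and 62.4 FPKM with SFA, a 7.22-fold difference (95% counting interval 6.85 to 7.62). HMOX1, which breaks down heme, stood at 17.9 and 48.3 FPKM (2.69-fold, 2.51 to 2.89), and SLC7A11, the cystine carrier that feeds glutathione synthesis, at 4.72 and 19.4 FPKM (4.12-fold, 3.81 to 4.45). OSGIN1, an oxidative stress-induced growth inhibitor, stood at 0.85 and 8.96 FPKM (10.5-fold, 8.43 to 13.3). Among the genes with the largest negative difference were ALPI, the intestinal alkaline phosphatase, at 8.26 FPKM with DMSO and 0.31 FPKM with SFA (26.7-fold lower, 15.8 to 49.2), and A2M, the protease inhibitor alpha-2-macroglobulin, at 127 and 24.5 FPKM (5.19-fold lower, 5.0 to 5.39). Of 11680 genes, 159 were at least 2-fold higher and 157 at least 2-fold lower in the SFA library. Leaving out genes that overlap another gene left 55 and 48, and AKR1C1 and SLC7A11 are among the overlapping genes, so their values are uncertain.

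All 31 measured NRF2 targets were higher in the SFA library, 15 of them at least 2-fold, with a median log2 difference of 0.88 (percentile 100; central 95% of random lists −0.05 to 0.14). Genes of MAPK feedback, which growth factor signalling through ERK turns on, had a median of 0.68 (percentile 100), and 12 of 14 were higher. ETV4, an ETS transcription factor, stood at 1.46 FPKM with DMSO and 13.1 FPKM with SFA (8.98-fold, 7.73 to 10.5), its relative ETV5 at 2.82 and 12.6 FPKM, FOSL1 at 0.579 and 2.88 FPKM, and PHLDA1 at 0.552 and 2.76 FPKM. In the integrated stress response, the ATF4-centred programme of amino acid shortage and protein stress, 30 of 32 genes were higher (median 0.37, percentile 100). CHAC1, a glutathione-degrading enzyme, was 3.10-fold higher, asparagine synthetase ASNS 2.01-fold and DDIT3, which encodes CHOP, 2.47-fold, and ATF3 stood at 1.69 and 2.01 FPKM. Among NF-kB targets (median 0.25, percentile 99.7; 13 of 15 higher), RELB was 5.95-fold, IL6 4.98-fold, NFKB2 2.84-fold and ICAM1 2.32-fold higher, while CCL2 stood at 8.74 and 4.54 FPKM and IER3 at 164 and 119 FPKM. Among YAP targets (median 0.24, percentile 99.8; 14 higher and 7 lower), CTGF (CCN2), a matricellular protein gene, stood at 9.32 and 43.3 FPKM and CYR61 (CCN1) at 31.0 and 72.1 FPKM, but PTPN14 at 13.7 and 7.96 FPKM. The NF-kB and YAP lists no longer stood apart at a filter of 5 FPKM (percentiles 96.6 and 99.3) or without overlapping genes (95.9 and 98.8), and with random lists matched on gene length too NF-kB targets lay at 99.3.

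Genes of lipid synthesis were lower in the SFA library. Of 22 genes in the cholesterol synthesis list, 21 were lower (median −0.32, percentile 0), with HMGCS1, an early enzyme of the mevalonate pathway, 1.68-fold lower and mevalonate kinase MVK 1.72-fold lower. In fatty acid synthesis (median −0.33, percentile 0.01), 10 of 15 genes were lower: SCD, the stearoyl-CoA desaturase, stood at 224 FPKM with DMSO and 110 FPKM with SFA, SREBF1, a regulator of lipid synthesis, at 24.9 and 11.9 FPKM, and FASN, the fatty acid synthase, at 255 and 166 FPKM, whereas ELOVL5 was 1.81-fold higher. Without overlapping genes the fatty acid list lay at percentile 0.575. Of 31 mitosis genes, 24 were lower (median −0.21, percentile 0.01), among them TOP2A, a DNA topoisomerase, 1.65-fold lower (1.55 to 1.75), and the kinetochore gene CENPF 2.17-fold lower. The 32 DNA replication genes had a median of −0.02 (percentile 14.4). MKI67, a marker of cycling cells, stood at 4.57 and 3.23 FPKM, and CCND1, a G1 cyclin, at 35.2 and 50.3 FPKM.

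Fibroblast markers, epithelial markers and the metallothionein list stood apart below in the SFA library. Among 5 measured genes of the fibroblast marker list (median −0.82, percentile 0.02), COL3A1, a fibrillar collagen, stood at 8.47 FPKM with DMSO and 1.49 FPKM with SFA (5.68-fold lower, 4.88 to 6.65), PDGFRB was 2.43-fold lower and COL1A1 1.89-fold lower, while THY1 was 1.51-fold higher. The keratins KRT8 and KRT18, among the 8 epithelial markers measured (median −0.27, percentile 0.44), were 1.87-fold and 1.83-fold lower and KRT7 was 1.37-fold higher. This list left its place apart with random lists drawn without matching (percentile 1.06) and with a pseudocount of 0.1 (percentile 0.64). In the metallothionein list, 4 metallothioneins and the zinc transporter SLC30A1 (median −0.68, percentile 0.02), MT1G was 3.45-fold lower and MT1E stood at 181 and 113 FPKM, and MT2A was 1.23-fold higher. Apoptosis promoters had a median of 0.27 (percentile 99.99), with BAX 1.86-fold higher, and apoptosis inhibitors a median of −0.23 (percentile 1.63), although BCL2L1, which encodes BCL-XL, stood at 1.07 and 10.0 FPKM (9.37-fold, 7.85 to 11.3). Hypoxia and glycolysis genes had a median of 0.17 (percentile 99.7), with ANGPTL4, a lipoprotein lipase inhibitor, 13.7-fold higher but CA9 2.10-fold lower. That percentile was 98.2 at a filter of 5 FPKM, 98.96 with a pseudocount of 0.1 and 96.4 without overlapping genes, and for apoptosis promoters it was 98.6 without overlapping genes.

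Most of the other lists did not stand apart in the SFA library. The p53 targets had a median of 0.06 (percentile 83.6): CDKN1A, the p21 gene, stood at 19.2 FPKM with DMSO and was 1.01-fold lower with SFA (0.947 to 1.08), MDM2 stood at 1.26 and 1.18 FPKM, while GDF15, a stress cytokine, was 3.17-fold higher. Medians were −0.09 for DNA damage repair, −0.03 for endoplasmic reticulum chaperones, 0.09 for the heat shock response, 0.12 for the interferon response, 0.06 for autophagy and lysosome, 0.15 for proteasome subunits (percentile 98.4), −0.06 for tubulins, −0.01 for mesenchymal markers, −0.02 for Wnt targets, −0.06 for immediate early genes, 0.05 for ribosome biogenesis and MYC targets and 0.03 for nuclear oxidative phosphorylation genes. Without overlapping genes proteasome subunits stood apart above (percentile 99.9) and Wnt targets below (0.2). Within these lists, SQSTM1, an autophagy receptor, stood at 32.2 and 87.0 FPKM. The 46 ribosomal protein genes had a median of 0.03, which turned to −0.00 under median-ratio scaling. AhR targets had a median of 0.37 (percentile 99.47, just inside the limit, but 99.76 with a pseudocount of 0.1, 99.68 against a protein-coding background, 99.54 under median-ratio scaling and 99.85 with gene length matched), and CYP1A1, their best known member, stood at 0.17 and 0.79 FPKM. All 6 measured AhR targets overlap another gene. Their values are therefore uncertain, and the list could not be placed without overlapping genes. A further 3 lists stood apart in the SFA library. Replication-dependent histones had a median of −0.08 (percentile 0, but 5.51 without matching and 0.52 without overlapping genes) and small nuclear and nucleolar RNA a median of −0.19 (percentile 0.13, but 1.5 without matching and 0.515 with gene length matched). The latter list also holds TERC, the RNA of telomerase, with 2790 counts with DMSO and 6 with SFA. TERC overlaps another gene, and its values are uncertain. Mitochondrially encoded genes had a median of 0.32 (percentile 99.9), with 11 of 13 higher. Of the gastric and intestinal differentiation list 3 genes were measured (median −0.44), with MUC1 2.57-fold lower, CDX2 1.54-fold lower and GATA6 2.81-fold higher. CDH1, the E-cadherin gene, stood at 0.147 and 0.162 FPKM. No leukocyte, erythroid, endothelial or hepatocyte marker reached 1 FPKM in any library (highest values 0.767, 0.469, 0.507 and 0.180 FPKM).

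The rest of the genes with the largest differences between SFA and DMSO included genes whose locus holds others. TMEM164, a membrane protein gene with no overlapping gene, stood at 0.85 FPKM with DMSO and 9.42 FPKM with SFA (11.1-fold, 9.53 to 12.9). ALPP, the placental alkaline phosphatase, stood at 54.8 and 10.0 FPKM and PXDC1 at 28.3 and 4.82 FPKM. CD24, a cell surface glycoprotein gene, had 5196 counts with DMSO, 354 with SFA and 2822 with SFE, and the histone gene HIST1H4H had 5596, 132 and 4657. NUDT3 had 2290, 16 and 1570 counts, and the read-through gene RPS10-NUDT3, listed at 0, 179 and 1, took up 11.2% of the counts missing with SFA. TMEM189-UBE2V1, another read-through gene, was listed at 0 with SFA against 623 counts with DMSO, at least 151-fold lower from a floor of 3 counts. PIGY had 1, 41 and 1 counts (56.4-fold higher with SFA, interval 9.57 to 2282). TMEM265 and the clone-named genes RP13-1032I1.10 and RP11-385D13.1 were higher with SFA, and XXbac-BPG32J3.22 and RP11-552F3.12 were lower. These 5 overlap other genes, and their values are uncertain. ALPI, TMEM164, HIST1H4H and CD24 overlap no other listed gene, whereas OSGIN1, ETV4, BCL2L1, ALPP, PXDC1 and A2M do.

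The comparison of SFE with DMSO asked the same of SFE at 18 µM. NRF2 targets were again higher: AKR1C1 stood at 8.63 FPKM with DMSO and 41.6 FPKM with SFE (4.82-fold, 4.57 to 5.10), HMOX1 at 17.9 and 35.1 FPKM (1.96-fold, 1.82 to 2.10), OSGIN1 at 0.85 and 4.31 FPKM (5.06-fold, 3.99 to 6.48) and SLC7A11 at 4.72 and 14.1 FPKM (2.99-fold, 2.76 to 3.25). BCL2L1 stood at 8.97 FPKM with SFE, 8.37-fold above DMSO (7.0 to 10.1), TMEM164 at 9.32 FPKM, BLCAP at 7.81 FPKM against 0.60 with DMSO and H2AFJ (H2AJ), a histone variant gene, at 7.74 FPKM against 0.81. ALPI was 18.7-fold lower (12.0 to 30.8), ALPP 5.03-fold lower and PXDC1 4.88-fold lower. At least 2-fold, 160 genes were higher and 118 lower in the SFE library, and 47 and 33 without overlapping genes.

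Of 31 NRF2 targets, 30 were higher in the SFE library, 7 of them at least 2-fold (median 0.57, percentile 100). AKR1C3, whose 2 identifiers overlap each other and AKR1C1, had counts of 739 with DMSO, 2241 with SFA and 803 with SFE under one identifier and 109, 418 and 974 under the other, so its value is uncertain. MAPK feedback genes had a median of 0.73 (percentile 100), with ETV4 at 9.52 FPKM (6.52-fold, 5.58 to 7.63) and ETV5 at 10.9 FPKM. The integrated stress response had 28 of 32 genes higher (median 0.34, percentile 100), with DDIT3 2.47-fold, CHAC1 2.29-fold and ASNS 1.92-fold higher. NF-kB targets (median 0.26, percentile 99.7; 13 of 15 higher) included IL6 at 5.11-fold and RELB at 4.92-fold, with CCL2 lower at 4.12 FPKM, and YAP targets (median 0.26, percentile 99.9; 16 higher and 5 lower) included CTGF at 3.91-fold and CYR61 at 2.05-fold. Cholesterol synthesis (median −0.23, percentile 0, 21 of 22 genes lower), fatty acid synthesis (−0.21, percentile 0.07) and mitosis (−0.24, percentile 0, 27 of 31 genes lower) stood apart below, with SCD 1.68-fold, FASN 1.45-fold, TOP2A 1.70-fold and the spindle motor gene KIF11 1.79-fold lower. So did fibroblast markers (−0.59, percentile 0.06; COL3A1 3.53-fold lower), the metallothionein list (−0.56, percentile 0.06; MT1G 3.72-fold lower), epithelial markers (−0.25, percentile 0.22; KRT8 1.80-fold lower) and ribosomal proteins (−0.05, percentile 0.35). Without overlapping genes the percentiles were 94.7 for NF-kB targets, 97.7 for YAP targets, 0.87 for cholesterol synthesis, 2.1 for fatty acid synthesis and 2.7 for ribosomal proteins. At a filter of 5 FPKM NF-kB targets lay at 92.8 and ribosomal proteins at 0.825, and with unmatched random lists epithelial markers lay at 0.61 and ribosomal proteins at 4.12. Ribosomal proteins lay at 0.52 against a protein-coding background and at 0.77 with gene length matched.

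A set of genes lay further from DMSO in the SFE library than in the SFA library. MCL1, an inhibitor of apoptosis, stood at 15.4 FPKM with DMSO, 10.7 with SFA and 3.88 with SFE (3.97-fold lower than DMSO, 3.61 to 4.38). CITED2, a transcriptional co-regulator gene, was 5.07-fold lower, TAF7, a subunit of the general transcription factor TFIID, 6.4-fold lower and RPS15, a ribosomal protein gene, 2.60-fold lower. IMP3, which encodes a component of the U3 small nucleolar ribonucleoprotein, had 17, 21 and 1264 counts. The read-through gene URGCP-MRPS24 and CTD-2132N18.3 were also lower. Both overlap other genes, as do MCL1, TAF7 and IMP3, so the values of all of these are uncertain, while CITED2 and RPS15 overlap none.

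Of the 13 mitochondrially encoded genes, 4 were listed at 0 counts in the SFE library. MT-CO1 (MT, 5904 to 7445) was listed at 134786 counts with DMSO, 97155 with SFA and 0 with SFE, and MT-ND5 at 7633, 7710 and 0. MT-CO2 was listed at 810, 604 and 0 counts, and MT-ND4 at 143, 201 and 22427. How the counting gave zeros beside so high a count of MT-ND4 is not known from the sources used here, so the values of these genes are uncertain and are not taken as differences in expression. MT-ND1 stood at 1336, 1671 and 1725 FPKM and MT-CYB at 845, 1194 and 1116 FPKM with DMSO, SFA and SFE. The median of this list was 0.37 (percentile 100), but the mean was −1.31, with 8 genes higher and 5 lower, all 5 at least 2-fold. FPKM of the 13 genes summed to 10118, 11521 and 7828, and to 5168, 6514 and 6635 without MT-CO1, MT-CO2, MT-ND4 and MT-ND5. Their share of all counts was 1.21%, 1.35% and 0.743%.

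The remaining lists did not stand apart in the SFE library, although 4 of them lay outside the central 95% of random lists, AhR targets at percentile 98.9 (99.51 with gene length matched), proteasome subunits at 98.4, histones at 1.34 and apoptosis inhibitors at 1.5. All measured AhR targets overlap another gene, so their values are uncertain. Medians were 0.03 for DNA replication, −0.04 for histones, −0.05 for DNA damage repair, −0.02 for p53 targets, 0.03 for endoplasmic reticulum chaperones, 0.10 for the heat shock response, 0.31 for AhR targets, 0.06 for the interferon response, 0.10 for hypoxia and glycolysis, 0.07 for apoptosis promoters, −0.18 for apoptosis inhibitors, 0.09 for autophagy and lysosome, 0.14 for proteasome subunits, 0.07 for tubulins, 0.04 for mesenchymal markers, 0.11 for Wnt targets, 0.02 for immediate early genes, 0.04 for ribosome biogenesis and MYC targets, 0.04 for nuclear oxidative phosphorylation genes and 0.08 for small nuclear and nucleolar RNA. DNA replication, endoplasmic reticulum chaperones and immediate early genes turned to −0.01 under median-ratio scaling. The 3 measured gastric and intestinal genes had a median of −0.15. CDKN1A stood at 17.3 FPKM, MYC at 69.2 FPKM against 70.4 with DMSO, and ANGPTL4 was 9.59-fold and GDF15 2.77-fold higher. Without overlapping genes apoptosis promoters (median 0.44, percentile 99.7) and proteasome subunits (median 0.21, percentile 99.6) stood apart above.

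Both compounds were compared through their differences from the same DMSO library. NRF2, MAPK feedback, integrated stress response, NF-kB and YAP targets stood apart above and lipid synthesis, mitosis, fibroblast, metallothionein and epithelial genes below in both. The median of mitochondrially encoded genes stood apart above in both as well, with the uncertain values of the SFE library included. With overlapping genes left out, NF-kB, YAP and fatty acid synthesis genes stood apart in neither library. Cholesterol synthesis genes then did not stand apart with SFE. The fibroblast, metallothionein and epithelial lists kept fewer than 5 members in that setting and could not be placed. At least 2-fold, 83 genes were higher in both libraries and 71 lower in both, against 2.18 and 1.59 for independent lists, and none went opposite ways. Unchanged libraries that share 1 control gave means of 24.9 and 24.7 genes in simulation, and at most 38 and 41. Without overlapping genes 28 were higher and 17 lower in both, and no simulation was run for that setting. Across genes, which are not independent replicates, Pearson's r was 0.67 and Spearman's rho 0.72, where simulation gave a mean r of 0.50 and a highest r of 0.61. The covariance was 0.110, against 0.0558 in simulation (highest 0.0884). The simulation gave the DMSO library noise only as large as the difference between the treated libraries implies. A DMSO library that deviates more would raise the overlap and the covariance by itself. Part or all of the excess may therefore come from the shared DMSO library, which cannot be split. Of the 154 genes at least 2-fold away in both, 108 lay further from DMSO with SFA.

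**Figure D1:**
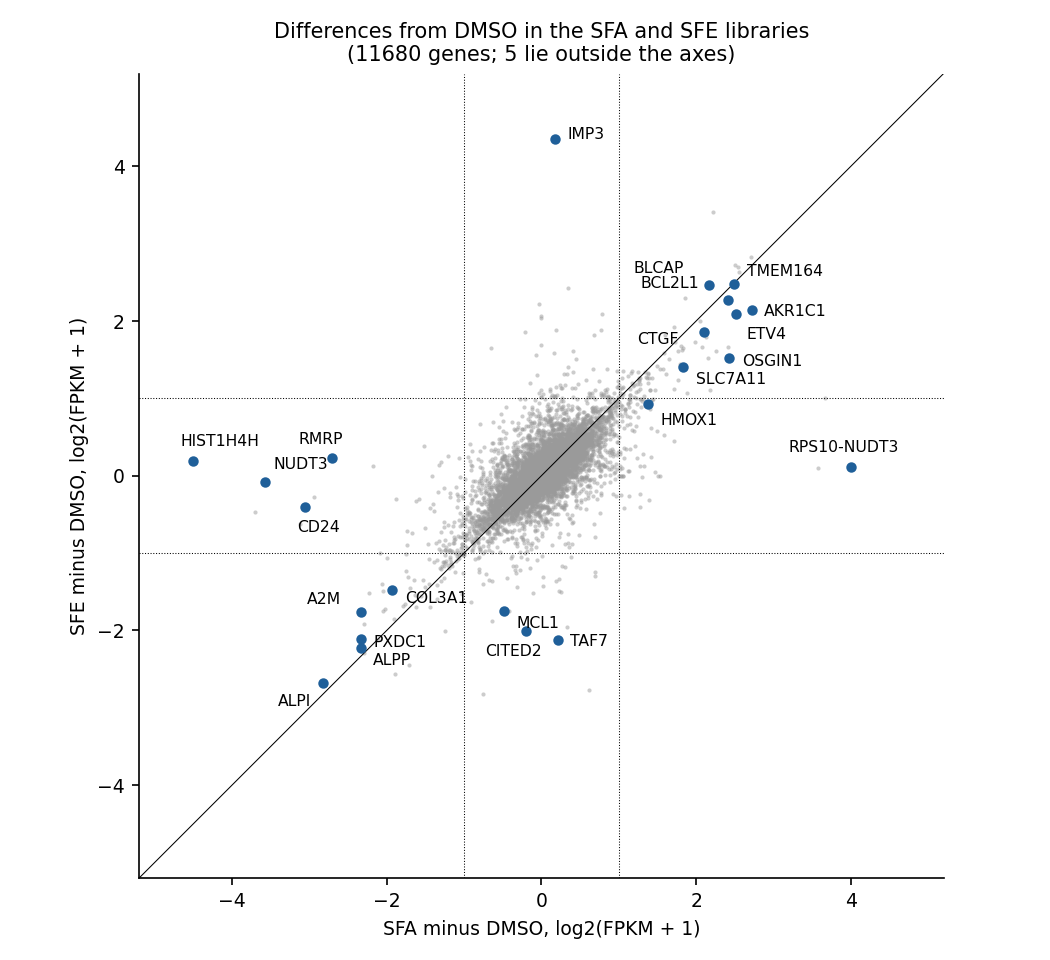
Each point is 1 of 11680 genes, placed by its log2(FPKM + 1) difference from DMSO in the SFA library (horizontal axis) and in the SFE library (vertical axis), with named genes labelled. Genes at least 2-fold away in both lie in the upper right (83) and lower left (71), and 5 genes, MT-CO1, MT-CO2, MT-ND4, MT-ND5 and TERC, lie beyond the axis limit of 5.2 and were picked for naming by that position, and their values are uncertain.

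**Figure D2:**
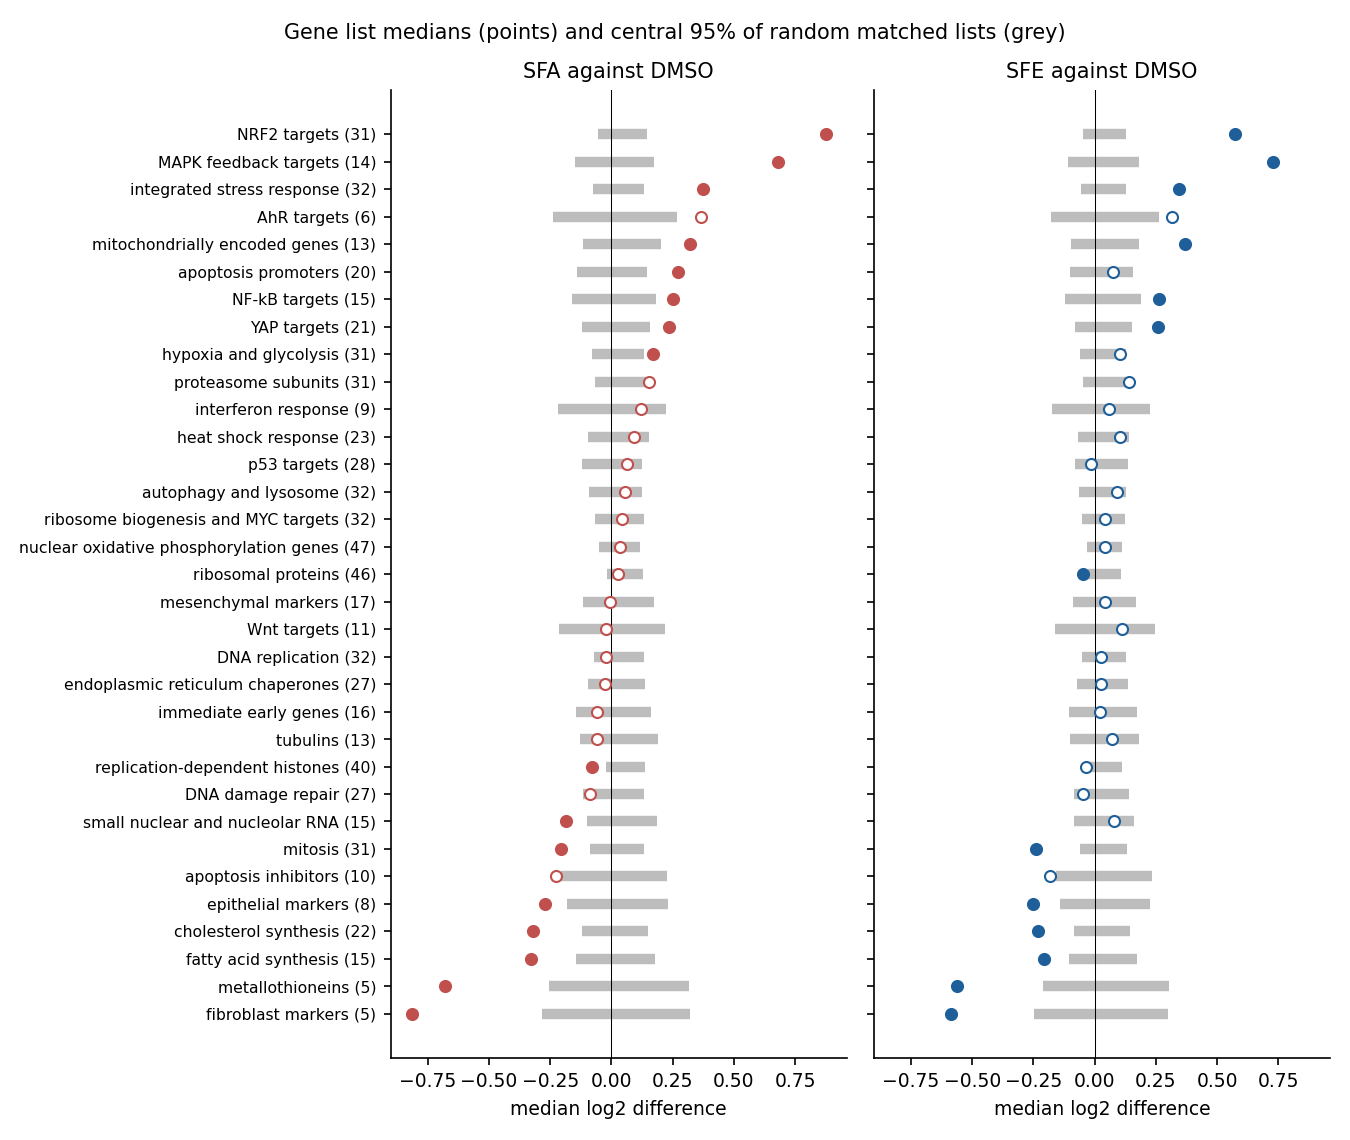
The median log2(FPKM + 1) difference of each fixed gene list is drawn for SFA and SFE against DMSO, with the central 95% of matched random lists as a grey bar, measured members in brackets and filled points for lists that stand apart. NRF2 targets (0.88 and 0.57) and MAPK feedback targets (0.68 and 0.73) lie highest, and fibroblast markers (−0.82 and −0.59) and the metallothionein list (−0.68 and −0.56) lowest.

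SFE at 18 µM and SFA at 12 µM were set side by side, and since the doses differ, dose and compound cannot be separated. NRF2 targets were lower with SFE than with SFA in 29 of 31 genes (median −0.19, percentile 0): AKR1C1 was 1.5-fold lower (1.45 to 1.55), OSGIN1 2.08-fold lower (1.82 to 2.38) and HMOX1 1.38-fold lower (1.29 to 1.47), while NQO1 stood at 112 FPKM with SFA and 110 FPKM with SFE. MAPK feedback genes (−0.14, percentile 0.12) and hypoxia and glycolysis genes (−0.08, percentile 0.34) were also lower with SFE, as were ribosomal proteins (−0.10, percentile 0, 38 of 46 genes). Cholesterol synthesis genes were higher in 21 of 22 cases (0.12, percentile 99.6), with MVK 1.38-fold higher, and histones (0.06, percentile 99.98) and mesenchymal markers (0.13, percentile 99.8; COL5A1 1.24-fold higher) stood apart above. Between the treated libraries 79 genes were at least 2-fold higher and 72 lower with SFE, and 19 and 25 without overlapping genes. The largest differences were MT-ND4, HIST1H4H, IMP3, NUDT3 and TMEM189-UBE2V1 upward and MT-CO1, MT-ND5, MT-CO2, RPS10-NUDT3 and PIGY downward. The mitochondrial values are uncertain from the counting, and all the others but HIST1H4H overlap other genes, which leaves their values uncertain too. An overlapping gene took up 0.0182% of the extra counts of IMP3 with SFE. For the counts missing with SFA it was 11.2% for NUDT3 and 102% for TMEM189-UBE2V1. HIST1H4H overlaps no listed gene, but reads shared with other histone H4 genes were not checked, so its value is uncertain as well. Without overlapping genes NRF2 targets, histones and ribosomal proteins still stood apart, while hypoxia and glycolysis lay at percentile 1.95, MAPK feedback at 6.17, cholesterol synthesis at 95.4 and mesenchymal markers at 47.7. At a filter of 5 FPKM hypoxia and glycolysis (17.6), MAPK feedback (1.6) and cholesterol synthesis (98.97) did not stand apart, nor with unmatched random lists did histones (87.1), cholesterol synthesis (98.2) and mesenchymal markers (98.2). With gene length matched histones lay at 97.98. Cholesterol synthesis also lay inside the limits with a pseudocount of 0.1 (99.2) and with median-ratio scaling (99.4).

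The other lists did not stand apart between SFE and SFA. Of these, 6 lay outside the central 95% of random lists: ribosome biogenesis and MYC targets at percentile 0.51, p53 targets at 0.67, mitosis at 1.06, the integrated stress response at 1.06, fatty acid synthesis at 99.1 and DNA replication at 97.9. Against a protein-coding background ribosome biogenesis (0.48) and p53 targets (0.46) stood apart below and fatty acid synthesis (99.51) above, and ribosome biogenesis did so below with a pseudocount of 0.1 (0.37), under median-ratio scaling (0.44) and with random lists matched on gene length too (0.15). At a filter of 5 FPKM ribosome biogenesis (0.08), p53 targets (0.25) and apoptosis promoters (0.23) stood apart below and immediate early genes (median 0.17, percentile 99.8) above, the opposite side from their median of −0.04 among all genes that entered, and so did the integrated stress response below without overlapping genes (0.09). Medians were 0.07 for DNA replication, −0.06 for mitosis, 0.00 for DNA damage repair, −0.06 for p53 targets, −0.06 for the integrated stress response, 0.02 for endoplasmic reticulum chaperones, −0.06 for the heat shock response, −0.01 for AhR targets, 0.04 for metallothioneins, 0.12 for fatty acid synthesis, 0.02 for the interferon response, −0.05 for NF-kB targets, −0.05 for apoptosis promoters, 0.00 for apoptosis inhibitors, 0.01 for autophagy and lysosome, −0.05 for proteasome subunits, 0.04 for tubulins, 0.03 for epithelial markers, 0.06 for Wnt targets, 0.01 for YAP targets, −0.04 for immediate early genes, −0.06 for ribosome biogenesis and MYC targets, 0.01 for mitochondrially encoded genes, −0.00 for nuclear oxidative phosphorylation genes, −0.00 for small nuclear and nucleolar RNA and 0.14 for fibroblast markers. Medians between −0.01 and 0.01 changed sign with the scaling in DNA damage repair, apoptosis inhibitors, autophagy and lysosome, YAP targets and mitochondrially encoded genes. Within these lists BAK1, a pro-apoptotic gene, stood at 20.5 FPKM with SFA and 8.22 FPKM with SFE (2.5-fold lower, 2.23 to 2.80), and KRT8, CTGF and DDIT3 differed by at most 1.19-fold.

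**Figure D3:**
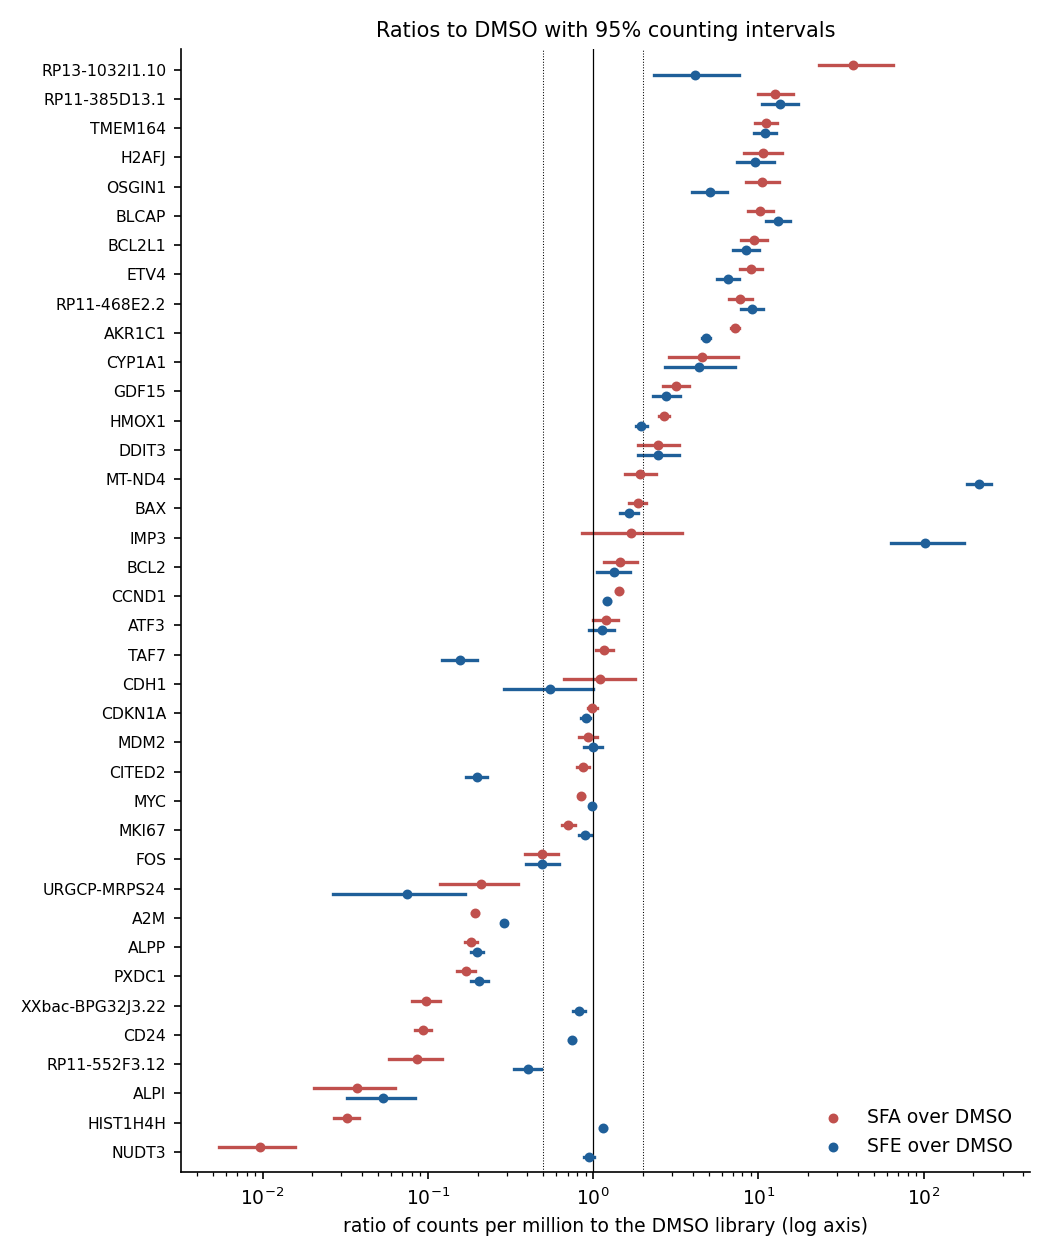
Ratios of count rates to DMSO are drawn on a log axis for 38 named genes with at least 4 counts in each library, for SFA and for SFE, with 95% counting intervals as bars. AKR1C1 (7.22 and 4.82) and ETV4 (8.98 and 6.52) lie above 1 in both libraries. Among the genes drawn that were at least 2-fold lower in both, ALPI lies furthest below, at 26.7-fold and 18.7-fold lower. Genes named only as members of a list, such as TERC, are not drawn.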

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

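Among the tests in this part, the search for an overlapping gene that takes up the missing or extra counts was chosen after the result was seen. The following genes and lists lay on opposite sides of DMSO with SFA and with SFE, and none of these differences was tested, since each group has 1 library. HIST1H4H, a histone H4 gene, differed by 4.70 (log2, SFE minus SFA). MT-CO2, a cytochrome oxidase subunit gene of the mitochondrial genome, differed by −6.04, where the SFE library lists it at 0. MT-ND5, also listed at 0 with SFE, differed by −8.29, and how the counting gave these zeros is not known, so both values are uncertain. RMRP, the RNA of a mitochondrial RNA-processing ribonuclease, differed by 2.93, and in the SFA library a second identifier at the same locus had 3162 counts against 33 with DMSO and 41 with SFE, which takes up 11.7% of the missing counts. RPS15 differed by −1.56 and TAF7, a general transcription factor subunit gene, by −2.34. For ribosomal protein genes the SFE median minus the SFA median was −0.072, but under median-ratio scaling both medians lay below DMSO (−0.09 with SFE and −0.00 with SFA), and for small nuclear and nucleolar RNA it was 0.26.

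Among genes with at least 100 counts in the highest library, 29 stood at least 2-fold apart in the SFA library alone and 33 in the SFE library alone, with the other libraries within 1.5-fold of each other. The counting interval reached 1 for 0% of these 62 genes, but the selection by count and fold fixes that outcome, so it decides nothing. Overlap with other genes as the whole cause was argued against, since 58.1% overlapped another gene against a median of 64.5% in random lists (53.2% to 75.8%). For the 36 that do overlap another gene, that gene took up at least 50% of the counts missing or in excess in 27.8% of cases, among them TMEM189-UBE2V1, where TMEM189 held extra counts equal to 102% of those missing. No share among random genes was set beside it. Some of these cases went beyond a transfer of the same reads, as with ARF3 at 2768% of the extra counts of RP11-302B13.5. A shift of reads between overlapping genes therefore stays open for part of that set. A difference between the cultures, or between the compounds, also stays open because neither can be told apart from a single library's deviation.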

How the results depend on the processing

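Leaving out genes that overlap another gene, leaving out genes at 0 counts in 1 library, asking for a whole counting interval beyond 2-fold and matching random lists on gene length too were chosen after the results were seen. No paired analysis was possible because each group has 1 library. Of all results 1 came to stand apart on the side opposite to its main median. Immediate early genes, SFE against SFA, had a median of 0.17 (percentile 99.8) at a filter of 5 FPKM against −0.04 (percentile 7.44), and the cause was not tested. The list medians near 0 that changed sign with the scaling, given above, are not counted here. Counts are given as higher and lower for SFA against DMSO, SFE against DMSO and SFE against SFA in turn. A pseudocount of 0.1 gave 452 and 374, 464 and 282, and 273 and 202, with 255 higher and 159 lower in both and an excess covariance of 0.0951, since it shrinks low values less. A pseudocount of 5 gave 46 and 35, 37 and 33, and 17 and 20. A 1.5-fold limit gave 626 and 545, 624 and 406, and 336 and 254 (331 and 267 in both), and a 4-fold limit 23 and 22, 20 and 16, and 16 and 10 (12 and 6 in both). With fewer genes entering, a filter at 5 FPKM gave 98 and 95, 94 and 72, and 40 and 37, a mean of at least 5 FPKM 52 and 26 in both, and protein-coding genes alone 101 higher for SFE against DMSO and 40 higher for SFE against SFA. Deposited counts in place of FPKM gave 312 and 328, 284 and 258, and 126 and 110. That setting also changed the filter to a minimum of 20 counts, so 14230 genes entered against 11680. Counts are not divided by gene length either, so the pseudocount acts on another scale than with FPKM. The larger numbers therefore come with changes in the design, and the share of each change was not tested. Without overlapping genes the counts were 55 and 48, 47 and 33, and 19 and 25, with 28 and 17 in both, and 8, 7 and 4 lists stood apart, of which 6, 5 and 3 also did so among all genes; only 26 of 33 lists kept 5 members, and 4, 3 and 0 of those that stood apart among all genes could not be placed. With unmatched random lists 4 lists stood apart in SFE against SFA; the cause was not tested. Counts of genes stayed within 1.5 times under the 3 scalings, with identifiers summed, with no filter, and under the other 2 added settings. Of the values of the 165 named genes under these settings, 5266 stayed on the same side of the limit, 79 crossed it outward and 49 inward, and of single lists 599, 20 and 40. Many of these genes were named for large differences, so the shares do not describe all genes. Genes that a setting dropped are not counted, and 198 values remained without overlapping genes. With gene length matched 15, 13 and 7 lists stood apart, of which 14, 12 and 6 also did so without it. Scaling moved the median of all genes by less than 0.1. Depth limits genes near 0.220 CPM in the treated libraries, the level of 3 counts, and below that a difference was not detectable.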

Other observations

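The tests of the DMSO library's deviation, the test of mitosis against replication genes, the scan of annotated pathways and families and its repeat with gene length matched were chosen after the results were seen, and the genes named in the next 2 paragraphs were chosen after their values were seen. Beyond the fixed lists, 253 annotated KEGG pathways with 10 to 300 measured genes were scanned. With SFA, 6 pathways stood apart above and 29 below, with SFE 4 and 14, against 2.53 expected per comparison for lists of randomly drawn genes. Co-regulated genes of a pathway can deviate together in a single library, so 2.53 is not the number expected without a treatment effect. Pathways also share genes, so those that stood apart are not independent of each other. Differences from DMSO went down with gene length across genes (rho −0.147 with SFA and −0.146 with SFE), and among random lists matched on length too 8 and 17 pathways stood apart with SFA and 6 and 10 with SFE. Glutathione metabolism, 33 genes of which 5 are also in the NRF2 list, had a median of 0.19 with SFA (percentile 99.9) and 0.14 with SFE (percentile 98.9). Glutathione reductase GSR stood at 50.2, 124 and 100 FPKM with DMSO, SFA and SFE, and both subunits of glutamate-cysteine ligase were higher, GCLC at 1.67, 5.51 and 3.93 FPKM and GCLM at 5.62, 14.2 and 10.7 FPKM. GPX4, which reduces lipid peroxides, went the other way at 137, 111 and 107 FPKM. Xenobiotic metabolism by cytochrome P450 (20 genes) had medians of 0.29 (percentile 99.96) and 0.30 (percentile 99.98), with the epoxide hydrolase EPHX1 at 22.2, 49.7 and 41.9 FPKM.

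Genes of cAMP signalling were lower in both libraries (88 genes, medians −0.14, percentile 0, and −0.08, percentile 0.07, or 0.01 and 0.11 with length matched). PDE3A, a cyclic nucleotide phosphodiesterase, stood at 19.2, 4.99 and 7.61 FPKM. Of 13 genes picked by the name PDE alone, whatever they act on, 12 were lower with each compound (medians −0.20, percentile 1.63, and −0.27, percentile 0.11, or 3.09 and 0.055 with length matched). Of 15 collagen genes, 11 were lower with each compound (medians −0.31, percentile 0.02, and −0.26, percentile 0.03, or 0.085 and 0.04 with length matched), and the SFE library lay closer to DMSO than the SFA library did (0.18 for SFE minus SFA, percentile 99.7). In arginine biosynthesis (10 genes, medians −0.19, percentile 1.5, and −0.25, percentile 0.12, or 1.14 and 0.12 with length matched), CPS1, the first enzyme of the urea cycle, stood at 51.3, 20.7 and 27.0 FPKM and ASS1 at 91.5, 68.8 and 71.3 FPKM. Axon guidance genes had medians of −0.11 (percentile 0.15) and −0.07 (percentile 0.07), or 0.15 and 0.14 with length matched, with SEMA6B at 2.28, 0.270 and 0.795 FPKM. Subunits of the V-ATPase proton pump, 16 genes, had a median of 0.22 with each compound and stood apart with SFE (percentile 99.54) and, once length was matched, with SFA (99.42 before and 99.54 after), and 75 mitochondrial ribosomal protein genes had a median of 0.11 with each without standing apart (percentiles 99.2 and 99.38, or 95.1 and 96.1 with length matched).

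NRF2 targets were higher in both treated libraries. Reads shared among AKR1C paralogs or overlapping genes were argued against as the whole cause: without them 12 members kept medians of 0.90 with SFA and 0.53 with SFE, both at percentile 100. A deviation of the single DMSO library cannot be told apart from a treatment effect for the side of DMSO on which both lie, where the lower median was 0.57. The DMSO library cancels from SFE minus SFA, so the median of −0.19 there (random lists −0.06 to 0.06) could not test it. A deviation of the single SFA or SFE library could give that distance. It cannot be told apart from a difference between the compounds or their doses. As a hypothesis, both compounds may raise NRF2 activity, more so at 12 µM SFA than at 18 µM SFE, which repeat cultures with their own DMSO controls would test.

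Mitosis genes were lower in both treated libraries. A trend with gene length was argued against, since among random lists matched on expression and length the higher of the 2 percentiles was 0.01. Fewer cycling cells might lower replication and mitosis genes alike. The mitosis median minus the replication median was −0.27 with SFE (percentile 0) and −0.18 with SFA (percentile 1.25). Only the SFE value lay past the limit for standing apart. Whether both lists move alike when fewer cells cycle was not checked, so this test cannot decide and that explanation stays open. A deviation of the DMSO library cannot be told apart either, since that library enters both differences. It cancels from SFE minus SFA, so the median of −0.057 there (percentile 1.06) could not test it. A smaller share of cells in mitosis is a candidate explanation that these data leave untested.

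At 110 genes the DMSO library stood apart from both treated libraries, 49 higher and 61 lower in DMSO, against 29 and 33 genes for the SFA and SFE libraries. Among them were TERC, which overlaps another gene and whose values are uncertain, with 2790, 6 and 5 counts, the ferritin light chain gene FTL at 507, 1122 and 1047 FPKM, S100A10 at 54.3, 131 and 132 FPKM, and MTCO1P12, a nuclear copy of a mitochondrial gene, with 634, 3137 and 3397 counts. MTCO1P12 overlaps another gene as well, so its values are uncertain too.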
